A study of Mus musculus with 6 samples.

How the data were processed

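RNA of 6 samples of xCT knockout mouse embryonic fibroblasts from the C57BL/6J strain, taken with TRIzol, was made into stranded libraries of messenger RNA with the TruSeq Stranded mRNA kit, per the labels' protocols. The labels give an age of 12 days. The deposited table gives 1 value per gene and library, in FPKM by the submitters' processing notes and by the values, since the file header names no unit. Those notes name the mouse build mm10, STAR 2.5.4, Cufflinks and Cuffdiff 2.2.1, without saying what each did. The gene annotation, the filters, any further scaling and whether counting used strand were not given in the sources used here. FPKM divide fragments by transcript length and library depth, so a transcript that takes a larger share of one library lowers all others there, and they are not counts, so no count model was used.

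The table held 21853 genes. All of their Ensembl identifiers were found in the GENCODE M21 annotation of the same build, where all 21853 are protein-coding genes, and no transcript of the mitochondrial genome was among them. That annotation gave coordinates, transcript length, GC content and overlapping exons. A symbol stood on more than 1 row for 24 genes, and the row with the highest mean was used for gene lists. Samples were grouped by their labels as control (water, n = 3) or RCE (red clover extract, n = 3).

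Depth was recovered from the low values. For genes with 1 annotated transcript, FPKM times transcript length and depth must be a whole number of fragments. The depth at which values between 0.02 and 0.5 FPKM came out whole, within 0.1 of a fragment, was 54300000, 49500000 and 49450000 fragments in control replicates 1, 2 and 3, and 45700000, 58950000 and 56150000 in RCE replicates 1, 2 and 3. At these depths 99.71 to 100% of 348 to 375 values per library were whole, against 15.3 to 19.4% at other depths. Fragments recovered for these genes were used to check whether 2 libraries could be the same one. Control replicates 2 and 3 differed by a chi-square of 5.05 per degree of freedom and RCE replicates 2 and 3 by 2.87, more than the 1 of counting error alone, and every other pair within a group differed by more (22.1 to 29.6). This covers counting error only, since amplified copies of a fragment are not independent molecules, so it does not show that libraries came from separate cultures. All 6 libraries were used as replicates because the labels give them as such.

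Groups were compared with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with an intensity trend in the prior variance, for the 10870 genes with a mean of at least 1 FPKM over the 6 libraries. Tests were 2-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, without a block. Gene lists were compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted over the 34 of 41 lists with at least 5 kept genes, and again with the correlation estimated per list. With the estimated correlation 2 lists passed, hypoxia targets and glycolysis, and 0 passed when the replicate block was added (adjusted p of at least 0.225). That form of camera also tests on the residual degrees of freedom of the fit, few with 6 libraries and fewer with the block. Its p rose even where the estimated correlation was below the preset one. Glycolysis, at -0.0118, went from an adjusted p of 2.30e-10 to 0.0318, and fibroblast markers, at -0.0442, from 3.75e-05 to 0.0584. Calls lost with it therefore do not measure correlation between genes alone. The level of Slc7a11 was compared by an exact permutation test.

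The groups share replicate numbers 1 to 3, and nothing in the labels says what a number stands for. Deviations from the group means correlated across genes at 0.92, 0.62 and 0.68 for the pairs numbered 1, 2 and 3, so the numbers were taken to pair the libraries, and the fit with replicate number as a block is given where it changes a call or moves a count by over 1.5 times. RCE replicate 2 correlated more with control replicate 3 (0.72) and RCE replicate 3 with control replicate 2 (0.77), so the data separate replicate 1 from the others but do not order replicates 2 and 3.

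The text names, by a rule set before the data were examined, the 12 largest positive and 12 most negative changes among genes past the threshold with a mean of at least 5 FPKM in a group and no overlap between groups, leaving out gene model names, a fixed panel of 24 genes of iron, ferroptosis, NRF2 and aryl hydrocarbon receptor biology, and up to 4 members with the smallest p of each list. Some genes that the rule names are not reported here. The gene lists, tests and most alternatives were also set then. Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, the replicate block, array weights, each library left out, a fold limit of 1 on the log2 scale, an estimated correlation and the fry rotation test. Leaving out both replicate 1 libraries and correcting for GC content, with and without the block, the block with an estimated correlation and the paired test of Slc7a11 were added after seeing the data. The table holds no test by the authors to compare with, and tests for counts did not apply.

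On data simulated from the means of these 10870 genes with 200 changed genes, a residual SD of 0.08 and a replicate effect, limma recovered 93.2% of genes changed by 0.5, 100% of those changed by 1 and 100% of those changed by 2 on the log2 scale in the comparison of RCE with control, and called 0% of unchanged genes. With the block it recovered 100% of genes changed by 0.5, 100% of those changed by 1 and 100% of those changed by 2, and called 0.0656% of unchanged genes. Every simulated gene had the same residual SD, and its replicate effect was drawn independently. In the deposited data the spread varied between genes (2.41 prior degrees of freedom in limma) and 24.3% of kept genes were called. These rates therefore need not hold there. Figures were drawn with matplotlib 3.10.9.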

Results

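The libraries held messenger RNA of mouse embryonic fibroblasts (MEF), connective tissue cells grown from embryos, in which xCT had been knocked out. xCT, encoded by Slc7a11, is the subunit of the cystine/glutamate antiporter that brings in cystine for glutathione synthesis, and its loss leaves cells prone to ferroptosis, a form of cell death driven by iron and lipid peroxidation. There were 6 libraries: 3 of cells given water (control) and 3 of cells given red clover extract (RCE). The dose, the length of exposure and the culture medium were not given in the sources used here. The deposited values were FPKM, fragments per kilobase of transcript scaled to the sequencing depth of the library, for 21853 genes. Steps between the low values gave a depth of 45700000 to 58950000 fragments per library, and 10766 to 10924 genes reached 1 FPKM in a library. The comparison addressed what the extract changes in these cells, with ferroptosis and the handling of iron as its subject. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these 6 libraries, which may be technical.

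Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614 on mm10) was close to the floor in every library. Its level was 0.013, 0.027 and 0.037 FPKM in control replicates 1, 2 and 3, and 0.009, 0.017 and 0.007 FPKM in RCE replicates 1, 2 and 3. At this depth 1 fragment on its longest annotated transcript is worth 0.0018 to 0.0024 FPKM, so few fragments lay behind each value. The group means, 0.0257 ± 0.0121 FPKM in control and 0.0110 ± 0.0053 FPKM with the extract (SD, n = 3), were not told apart by a 2-sided exact permutation test (p = 0.2, where 0.1 is the smallest that 3 against 3 can give). The level was lower with the extract in 3 of 3 pairs of same-numbered libraries (2-sided paired exact permutation test, p = 0.25, which is the smallest that 3 pairs can give).

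Libraries of the 2 groups separated on the principal component that held 58.1% of the variance of log2(FPKM + 1) over 10870 genes with a mean of at least 1 FPKM. A component with 36.5% of the variance set replicate 1 of both groups apart from replicates 2 and 3. Pearson correlations across genes were 0.991 to 0.999 within groups and 0.982 to 0.990 between groups.

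**Figure D1:**
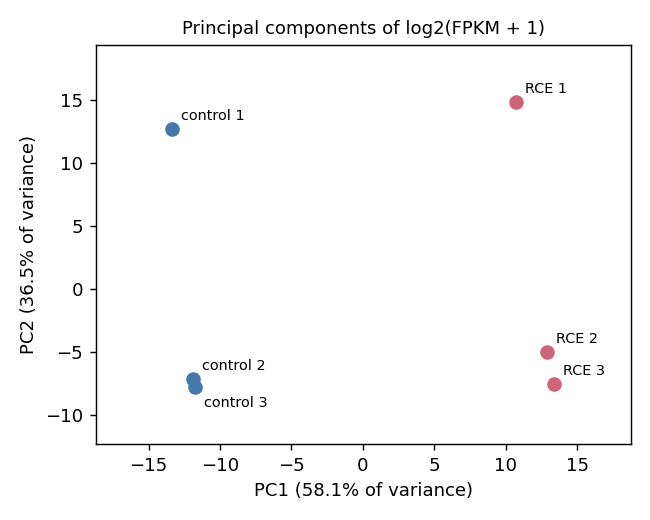
Scores of the 6 libraries on the first principal components of log2(FPKM + 1), control in blue and RCE in red. The horizontal axis (58.1% of the variance) separates the groups, and the vertical axis (36.5%) sets replicate 1 of each group above the rest.

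With the extract, transcripts of the hypoxia response and immediate-early genes had the lowest list medians, those of glycolysis, cholesterol synthesis and inflammatory signalling fell too, and those of DNA replication and mitosis rose. With an estimated correlation the hypoxia and glycolysis lists passed camera (adjusted p = 0.0318 for both), the immediate-early, inflammatory and DNA replication lists did not (adjusted p = 0.0584), nor did cholesterol synthesis and mitosis (adjusted p = 0.0827). With the replicate block as well, no list passed, and the lowest adjusted p was 0.225, in a test on few residual degrees of freedom. In limma with Benjamini-Hochberg adjustment, 1910 genes were higher and 736 lower at an adjusted p below 0.05, of which 7 and 60 moved by at least 1 on the log2(FPKM + 1) scale. All fold changes below are on that scale, as RCE minus control, and understate the change of genes with low values. With replicate number as a block the counts were 5060 higher and 1730 lower. The excess of higher calls, 72.2% of the total, rested on the scaling: the median change of all kept genes was +0.08, and with median-of-ratios scaling, which moved that median to 0.00, 911 genes were higher and 1082 lower (45.7% higher). The 3 values of one group all lay above those of the other for 42.2% of genes, where chance gives 10% if the pairing by number is ignored. Leaving out control replicate 2 gave 920 higher and 441 lower, control replicate 3 gave 855 and 440, RCE replicate 2 gave 677 and 399, and RCE replicate 3 gave 892 and 466. Without both replicate 1 libraries the counts were 4360 and 1481.

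**Figure D2:**
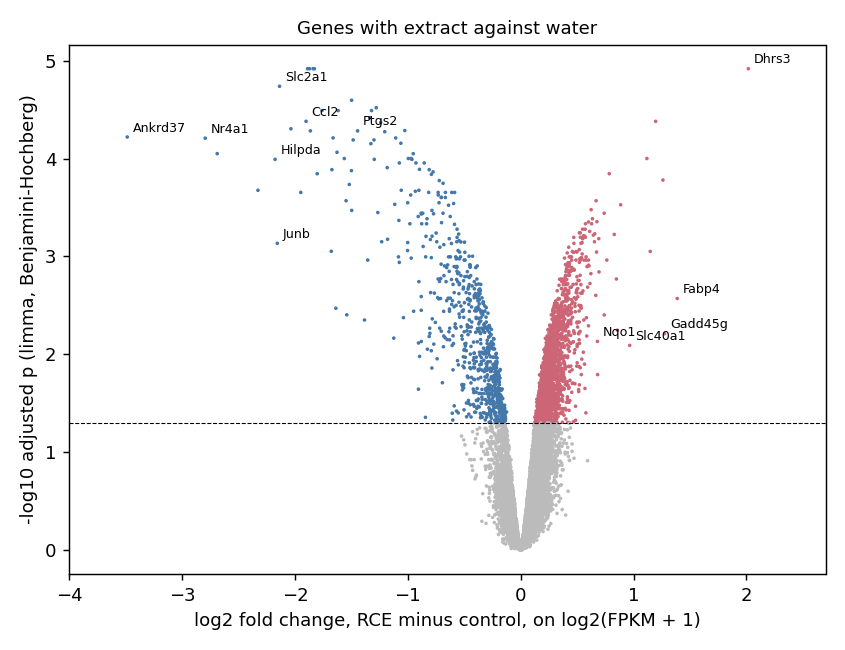
Change of each of 10870 genes with the extract, on the log2(FPKM + 1) scale (horizontal), against -log10 of the limma adjusted p (vertical), with the dashed line at 0.05. The 1910 higher genes are red and the 736 lower genes blue, and the genes furthest to the left include Ankrd37, Nr4a1, Hilpda, Junb and Slc2a1.

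Targets of hypoxia-inducible factor (HIF), the transcription factor stabilised in low oxygen, fell together. Of 33 measured members 28 were lower and 0 higher (29 lower when adjusted over the list alone, 31 lower and 2 higher with the replicate block). The median change was -0.72 (camera adjusted p = 8.46e-31, adjusted p = 0.0318 with an estimated correlation, and adjusted p = 0.225 with that and the block, which ends the call). Ankrd37 (ENSMUSG00000050914, chromosome 8, 45996902 to 46005707), a HIF target of the ankyrin repeat family, had the most negative change of the genes named by the rule and went from 12.3 ± 2.45 to 0.18 ± 0.0777 FPKM (SD, n = 3, log2 change -3.48, SE 0.14, adjusted p = 6.03e-05). Outside the list, Hilpda, a lipid droplet protein induced by hypoxia that the rule names for its size of change, went from 34.3 ± 3.36 to 6.82 ± 0.82 FPKM (log2 change -2.18, adjusted p = 1.02e-04). Other list members with the smallest p were Pfkfb3, which makes the activator of phosphofructokinase (-1.84), Egln3, a HIF prolyl hydroxylase (-1.76), and Ndrg1 (-1.34).

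Transcripts of glycolysis and the pentose phosphate pathway fell as well, with 14 of 26 members lower and 2 higher (15 and 2 adjusted over the list alone, 17 and 5 with the replicate block). The median was -0.32 (camera adjusted p = 2.30e-10, adjusted p = 0.0318 with an estimated correlation, and adjusted p = 0.225 with that and the block, which ends the call). Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), the glucose transporter GLUT1 and a member of both lists, went from 106 ± 4.09 to 23.3 ± 1.33 FPKM (SD, n = 3, log2 change -2.14, SE 0.06, adjusted p = 1.83e-05). The lactate exporter Slc16a3 went from 4.55 to 0.50 FPKM (-1.89, adjusted p = 1.21e-05). Hexokinase 2 (Hk2) changed by -1.23 and the liver-type phosphofructokinase (Pfkl) by -0.72. The nuclear-encoded subunits of oxidative phosphorylation, with 45 members measured, had none past the threshold in limma (0 higher and 0 lower, 1 and 0 at an unadjusted p under 0.05, 7 and 4 with the replicate block). Camera gave this list an adjusted p of 0.236.

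Immediate-early genes, the transcripts that growth factors and stress induce first, fell in 26 of 34 cases, and 1 rose (the same counts adjusted over the list alone, 28 lower and 2 higher with the replicate block). Their median change was -0.67 (camera adjusted p = 6.26e-24, and adjusted p = 0.0584 with an estimated correlation). The orphan nuclear receptor Nr4a1 went from 59.1 ± 6.82 to 7.67 ± 1.07 FPKM (log2 change -2.79, SE 0.11, adjusted p = 6.20e-05). The AP-1 components Junb and Fos changed by -2.16 and -1.50, Egr3 by -1.95, and the MAP kinase phosphatases Dusp6 and Dusp5 by -1.28 and -1.30. Outside the list, the rule also names Rgs16, a regulator of G protein signalling, which changed by -1.87, and Ereg, a ligand of the EGF receptor, by -1.86. Inflammatory and NF-kB targets were lower in 13 of 21 cases and higher in 0 (14 lower adjusted over the list alone, 16 lower and 2 higher with the block, median -0.20, camera adjusted p = 5.65e-12, and adjusted p = 0.0584 with an estimated correlation). The chemokine Ccl2 went from 22.1 ± 1.45 to 5.18 ± 0.346 FPKM (log2 change -1.90, adjusted p = 4.17e-05), and the changes of Nfkbiz and Lif were -1.18 and -0.97. The median of the inflammatory list was -0.034 with no low-value filter. Among glucocorticoid targets 8 of 15 were lower and 2 higher (9 and 3 adjusted over the list alone, median -0.34, camera adjusted p = 9.19e-06, and adjusted p = 0.0584 with an estimated correlation). Their median was -0.20 with no low-value filter, and -0.21 without control replicate 1, -0.52 without RCE replicate 1 and -0.20 without RCE replicate 2. The lower ones included the kinase Sgk1 (-1.56), the EGF receptor inhibitor Errfi1 (-1.33) and the transcription factor Cebpd (-1.35), while Angptl4 was higher.

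**Figure D3:**
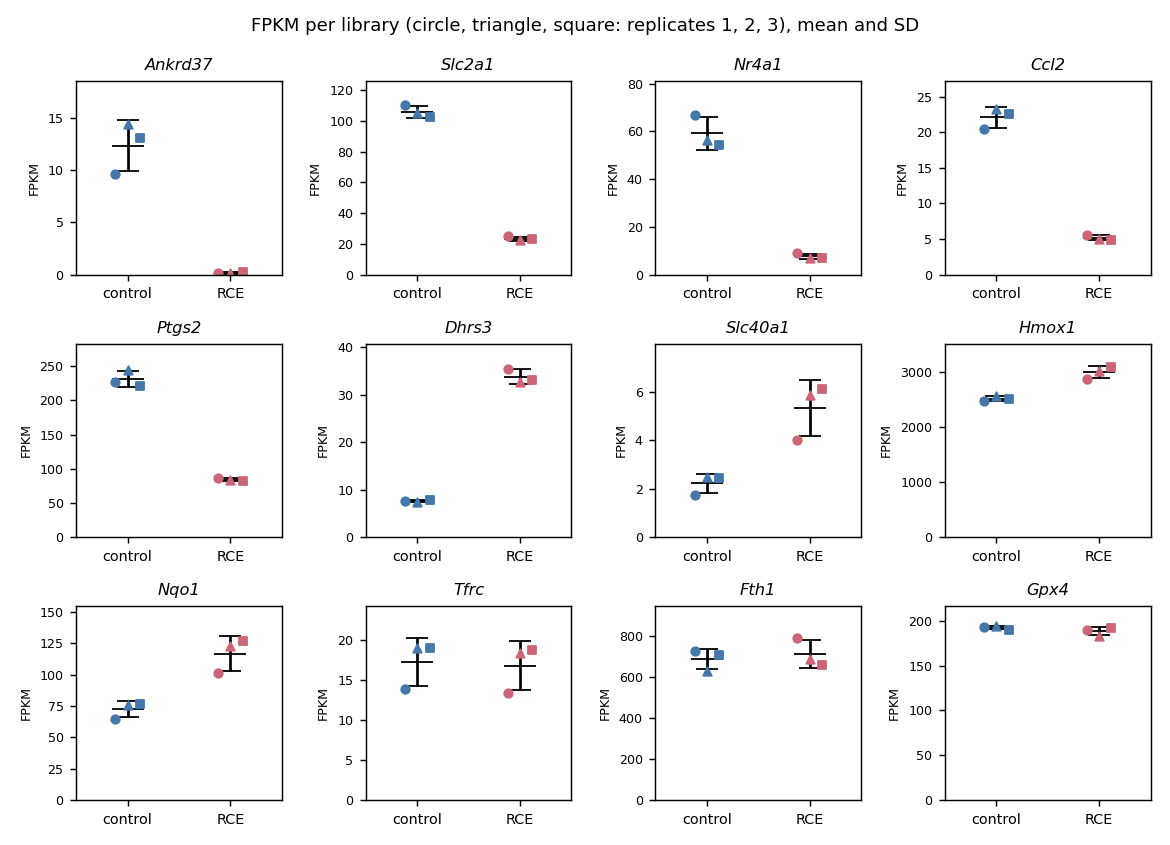
FPKM of 12 genes in each library (circle, triangle and square for replicates 1, 2 and 3; blue for control, red for RCE), with the mean and SD of each group (n = 3). Ankrd37, Slc2a1, Nr4a1, Ccl2 and Ptgs2 are lower and Dhrs3, Slc40a1 and Nqo1 higher in all 3 RCE libraries, while Tfrc, Fth1 and Gpx4 overlap between groups.

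Of the genes that handle iron, the exporter and 3 genes of haem turnover rose, a mitochondrial importer fell and the other measured members did not pass the threshold. Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523) encodes ferroportin, the iron exporter. It went from 2.22 ± 0.404 to 5.33 ± 1.15 FPKM (SD, n = 3, log2 change 0.97, SE 0.16, adjusted p = 0.0081). Of 25 members of the iron list 4 were higher and 1 lower (the same adjusted over the list alone, median 0.09), which did not stand out from other genes (camera adjusted p = 0.371). The fry rotation test, which does not compare with other genes, called the list upward (adjusted p = 5.82e-04). Over the alternatives that median ran from 0.021 with median-of-ratios scaling to 0.13 without control replicate 2. With the replicate block 12 were higher and 2 lower. The others higher were Blvrb, which reduces biliverdin (0.41, adjusted p = 0.00342), the haem transporter Slc48a1 (0.39, adjusted p = 0.0124) and Hmox1, haem oxygenase 1. The mitochondrial iron importer Slc25a37 was lower (-0.33, adjusted p = 0.00987). Hmox1 was abundant in both groups, at 2521 ± 47 and 3002 ± 106 FPKM (log2 change 0.25, adjusted p = 0.0261). Its call ended with no low-value filter (adjusted p = 0.217), median-of-ratios scaling (0.0889), quantile normalization (0.194) and GC correction (0.0789). It also ended without control replicate 1 (adjusted p = 0.0618), control replicate 2 (0.0771), control replicate 3 (0.0885), RCE replicate 2 (0.114) and RCE replicate 3 (0.103). With median-of-ratios scaling its change was 0.16. The call of Slc48a1 ended without control replicate 2 (adjusted p = 0.0547), control replicate 3 (0.0523) and RCE replicate 2 (0.0519), and that of Slc25a37 without RCE replicate 2 (adjusted p = 0.0528). Of 20 genes of iron-sulfur cluster and haem synthesis 3 were higher and 0 lower (the same adjusted over the list alone, median 0.07, camera adjusted p = 0.438). With the replicate block 8 were higher. The median ran over the alternatives from -0.004 with GC correction to 0.11 without RCE replicate 1. Cpox led (0.29, adjusted p = 0.00821), and its call ended with GC correction (adjusted p = 0.0651). The calls of Alad and Fech ended with median-of-ratios scaling (adjusted p = 0.0759 and 0.204) and quantile normalization (0.0565 and 0.248). They also ended without control replicate 2 (0.0605 and 0.108), control replicate 3 (0.0663 and 0.107) and RCE replicate 2 (0.0736 and 0.109). That of Fech ended as well without RCE replicate 1 (0.0592) and RCE replicate 3 (0.0646), and with GC correction (0.331).

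The messenger RNAs of the transferrin receptor, ferritin, the importers Slc11a2 and Slc39a14 and the iron regulatory proteins did not pass the threshold in limma without the block. The transferrin receptor Tfrc was at 17.3 ± 2.99 FPKM in control and 16.8 ± 3.02 FPKM with the extract (log2 change -0.04, SE 0.17, adjusted p = 0.898, 95% interval -0.44 to 0.37). With the replicate block and GC correction it was called lower (-0.14, adjusted p = 0.0024). Changes of the ferritin subunits were +0.05 for Fth1 (adjusted p = 0.735) and +0.15 for Ftl1 (adjusted p = 0.119, and 0.0163 with the replicate block), both of which have processed pseudogenes that could share reads. The importer Slc11a2 was at +0.13 (adjusted p = 0.171, and 0.00869 with the block), Slc39a14 at -0.10 (0.409, and 0.0239 with the block), and the ferritin receptor Ncoa4 at +0.07 (adjusted p = 0.617). The iron regulatory proteins Aco1 and Ireb2 were at +0.18 (adjusted p = 0.211, and 0.00159 with the block) and +0.15 (adjusted p = 0.411, and 0.00193 with the block). Without RCE replicate 1, Aco1 passed the threshold (0.26, adjusted p = 0.0423). Over the alternatives the changes ran from -0.18 without control replicate 1 to 0.11 without RCE replicate 1 for Tfrc, from -0.037 with median-of-ratios scaling to 0.10 without RCE replicate 3 for Fth1 and from 0.063 with median-of-ratios scaling to 0.17 without control replicate 1 for Ftl1. Those of the importers ran from 0.036 with quantile normalization to 0.17 without RCE replicate 1 for Slc11a2 and from -0.18 with median-of-ratios scaling to -0.028 without RCE replicate 1 for Slc39a14. For the others they ran from -0.024 with GC correction to 0.14 without RCE replicate 1 (Ncoa4), from 0.094 with median-of-ratios scaling to 0.26 without RCE replicate 1 (Aco1) and from 0.041 with GC correction to 0.25 without RCE replicate 1 (Ireb2).

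Among genes of ferroptosis execution and defence, Ptgs2, the cyclooxygenase often used as a marker of ferroptosis and also a member of the inflammatory list, changed most. It went from 231 ± 12.3 to 84.2 ± 1.88 FPKM (SD, n = 3, log2 change -1.44, SE 0.05, adjusted p = 5.22e-05). Of 23 members 3 were higher and 4 lower (3 and 6 adjusted over the list alone, 6 and 11 with the block), with a median of -0.03 (camera adjusted p = 0.00483, and adjusted p = 0.0827 with an estimated correlation). The list median was -0.010 with no low-value filter, -0.067 with a minimum mean of 5 FPKM, -0.12 with median-of-ratios scaling, -0.078 with quantile normalization, -0.065 with array weights and -0.12 with GC correction (also with the block), and -0.070 without control replicate 1, -0.047 without control replicate 2, -0.048 without control replicate 3, -0.046 without RCE replicate 1 and -0.072 without RCE replicate 3. The other lower members included Fdft1 (-0.31) and Nfe2l2, which encodes NRF2 (-0.42), and Dhodh was among the higher ones (+0.34). Gpx4, the peroxidase that removes lipid hydroperoxides, was at 192 ± 2.12 and 188 ± 4.45 FPKM (log2 change -0.03, adjusted p = 0.667). Acsl4, which loads polyunsaturated fatty acids, was at 17.7 and 17.7 FPKM (adjusted p = 0.969). With the replicate block and GC correction both were called lower (Gpx4 -0.08, adjusted p = 0.045, and Acsl4 -0.10, adjusted p = 0.0186). Changes of Lpcat3 and Aifm2 (FSP1) were +0.12 (adjusted p = 0.146, and 0.00913 with the block) and +0.23 (adjusted p = 0.0833, and 0.00627 with the block). Chac1, which degrades glutathione, was at -0.10 (adjusted p = 0.199, and 0.00964 with the block). With GC correction alone Chac1 was called lower (-0.16, adjusted p = 0.0475). Changes over the alternatives ran from -0.12 with median-of-ratios scaling to 0.056 with quantile normalization for Gpx4, from -0.10 with GC correction to 0.021 without control replicate 2 for Acsl4 and from 0.032 with median-of-ratios scaling to 0.15 without RCE replicate 3 for Lpcat3. They ran from 0.13 with quantile normalization to 0.31 without control replicate 2 for Aifm2 and from -0.19 with median-of-ratios scaling to -0.076 without control replicate 1 for Chac1. Aifm2 passed the threshold without control replicate 2 (adjusted p = 0.0355). The call of Fdft1 ended without control replicate 2 (adjusted p = 0.0535), control replicate 3 (0.0516) and RCE replicate 3 (0.0534). That of Nfe2l2 ended without RCE replicate 2 (adjusted p = 0.0639) and RCE replicate 3 (0.0549). That of Dhodh ended without control replicate 2 (adjusted p = 0.0535), control replicate 3 (0.058), RCE replicate 2 (0.067) and RCE replicate 3 (0.0538), and with quantile normalization (adjusted p = 0.0519). The call of the list ended with quantile normalization (adjusted p = 0.0803).

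More antioxidant genes under NRF2 were higher (8 of 29) than lower (2), the same adjusted over the list alone (median 0.18, camera adjusted p = 0.13). With the block 22 were higher and 3 lower. The NRF2 median ran from 0.11 with GC correction to 0.24 without RCE replicate 1. The quinone reductase Nqo1 went from 72.4 ± 6.52 to 117 ± 13.8 FPKM (log2 change 0.68, SE 0.11, adjusted p = 0.00738). The exporter Abcc4 (+0.39), thioredoxin reductase Txnrd1 (+0.28, adjusted p = 0.0126) and Gclm, the modifier subunit of glutamate-cysteine ligase (+0.32, adjusted p = 0.0115), were higher. Gclc, the catalytic subunit of that ligase (-0.45, adjusted p = 0.00364), and Ugdh (-0.88) were lower. Camera passed this list, upward, with quantile normalization (adjusted p = 0.00284), GC correction (0.0294) and the replicate block and GC correction together (0.0178). The call of Gclm ended with median-of-ratios scaling (adjusted p = 0.0507) and GC correction (0.104), and that of Txnrd1 without control replicate 3 (adjusted p = 0.0518), RCE replicate 2 (0.0649) and RCE replicate 3 (0.0575). The list of glutathione and thiol metabolism had 3 higher and 3 lower of 30 (the same adjusted over the list alone, camera adjusted p = 0.166; 10 and 7 with the block), among them Cdo1 (-0.38) and Ethe1 (+0.29). Targets of the aryl hydrocarbon receptor, which binds many plant compounds, were split: 3 higher and 4 lower of 12 (4 and 4 adjusted over the list alone, camera adjusted p = 0.13; 5 and 5 with the block). Cyp1b1 went from 94.5 to 158 FPKM (+0.74, adjusted p = 3.62e-04), while Tiparp was at -0.73 (adjusted p = 2.36e-04) and Ahr itself at -0.30 (adjusted p = 0.00718). Cyp1a1 was at 0.0937 ± 0.029 and 0.156 ± 0.0539 FPKM (SD, n = 3), under the minimum for the test. Oestrogen receptor targets, of interest because red clover holds isoflavones that bind this receptor, had 0 higher and 2 lower of 12 (the same adjusted over the list alone, median 0.07, camera adjusted p = 0.302; 5 and 3 with the block; median over the alternatives from -0.013 with median-of-ratios scaling to 0.083 without control replicate 1), the lower ones being Fosl2 (-0.67) and Ccn5 (-0.50).

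Transcripts of the cholesterol synthesis list fell, with 19 of 25 lower and 0 higher (the same adjusted over the list alone, median -0.30, camera adjusted p = 1.34e-16, and adjusted p = 0.0827 with an estimated correlation). Squalene epoxidase Sqle (-0.55), Idi1 (-0.47) and Nsdhl (-0.41) were among the members with the smallest p. Fatty acid synthesis and desaturation had 3 higher and 2 lower of 23 (the same adjusted over the list alone, camera adjusted p = 0.371; 10 and 7 with the block), with the desaturase Scd2 at -0.55 and Gpam at +0.32. Adipocyte genes were higher in 3 of 5 cases and lower in 0 (4 higher adjusted over the list alone, median 0.34, camera adjusted p = 0.0286, and adjusted p = 0.141 with an estimated correlation and 0.0643 with the replicate block). The call of that list also ended without RCE replicate 1 (adjusted p = 0.0521) and with no low-value filter (adjusted p = 0.317). Its median was 0.018 with no low-value filter. The fatty acid carrier Fabp4 went from 3.79 ± 0.633 to 11.6 ± 2.3 FPKM (log2 change 1.39, adjusted p = 0.00269), with Lpl at +0.57 and the nuclear receptor Pparg at +0.34. PPAR targets and fatty acid oxidation had 6 higher and 0 lower of 24 (the same adjusted over the list alone, median 0.10, camera adjusted p = 0.23; 14 and 3 with the block; median over the alternatives from 0.018 with median-of-ratios scaling to 0.18 without RCE replicate 1), including Angptl4, an inhibitor of lipoprotein lipase (+1.20, adjusted p = 4.17e-05), and Cpt1b (+0.41).

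Genes of DNA replication and mitosis rose. Of 33 G1/S and replication genes 26 were higher and 0 lower (29 and 1 adjusted over the list alone, 31 and 1 with the block, median 0.39, camera adjusted p = 2.17e-09, and adjusted p = 0.0584 with an estimated correlation). Of 40 G2/M genes 31 were higher and 0 lower (35 higher adjusted over the list alone, median 0.33, camera adjusted p = 4.18e-10, and adjusted p = 0.0827 with an estimated correlation). The members with the smallest p changed by +0.62 (Dtl), +0.52 (Uhrf1), +0.66 (the primase subunit Prim1) and +0.56 (the helicase subunit Mcm3) in the replication list, and by +0.52 (cyclin A2) and +0.55 (topoisomerase 2 alpha) in the mitosis list. The kinesin Kifc1 was among the 12 largest rises (+0.76). These transcripts were of low level, with Mcm3 at 6.5 and 10.02 FPKM. p53 targets were higher in 13 of 30 cases and lower in 3 (14 and 3 adjusted over the list alone, 21 and 3 with the block, median 0.14, camera adjusted p = 0.0322, and adjusted p = 0.171 with an estimated correlation and 0.0646 with the replicate block). That call also ended without control replicate 3 (adjusted p = 0.0511) and with array weights (adjusted p = 0.0542). Their median was 0.058 with median-of-ratios scaling and 0.079 with GC correction (also with the block). Ercc5 (+0.55), Plk2 (+0.41) and Gtse1 (+0.67) were higher and Plk3 (-0.61) lower. The p53 targets Cdkn1a and Mdm2 did not pass the threshold in limma. Cdkn1a was at +0.09 (adjusted p = 0.26, and 0.0229 with the block) and Mdm2 at -0.005 (adjusted p = 0.952, and 0.885 with the block). Ribosome biogenesis and MYC targets had 6 higher and 1 lower of 40 (4 and 1 adjusted over the list alone, 31 and 1 with the block, median 0.15, camera adjusted p = 0.0322, and adjusted p = 0.123 with an estimated correlation, 0.080 with median-of-ratios scaling and 0.0559 without control replicate 1). Their median was 0.063 with median-of-ratios scaling and 0.062 with GC correction (also with the block). Dkc1 (+0.33) and Cad (+0.34) were higher, and the lower member was Ldha, a lactate dehydrogenase gene (-0.73).

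More genes of the extracellular matrix fell than rose. In the collagen and matrix list 18 of 49 were lower and 2 higher (19 and 2 adjusted over the list alone, 31 and 5 with the block, median -0.15, camera adjusted p = 2.16e-11, and adjusted p = 0.0584 with an estimated correlation). Its median was -0.24 with median-of-ratios scaling. Col5a3 (-0.59), elastin (Eln, -0.53) and Col8a1 (-0.45) were lower, while the proteoglycan Ogn went from 17.9 ± 0.864 to 44.2 ± 3.22 FPKM (+1.26, adjusted p = 1.66e-04). Fibroblast markers were lower in 3 of 16 cases and higher in 0 (2 lower adjusted over the list alone, 11 lower and 1 higher with the block, median -0.14, camera adjusted p = 3.75e-05, and adjusted p = 0.0584 with an estimated correlation), the first of them Pdgfrb (-0.31, adjusted p = 0.0223), whose call ended without control replicate 2 (adjusted p = 0.0568), control replicate 3 (0.0607), RCE replicate 2 (0.0878) and RCE replicate 3 (0.0793) and with quantile normalization (adjusted p = 0.0565). Twist2 and Dcn, the other lower members, lost their calls too. Twist2 lost it without control replicates 1 and 2 and RCE replicates 2 and 3 (adjusted p = 0.0502 to 0.097). Dcn lost it when any 1 of the 6 libraries was left out (adjusted p = 0.0521 to 0.133). All 3 thus lost it without control replicate 2 and without RCE replicate 2. The median of fibroblast markers was -0.22 with median-of-ratios scaling and -0.22 with GC correction (also with the block). Metalloproteinases and ADAMTS had 3 lower and 2 higher of 17 (6 and 5 adjusted over the list alone, 8 and 5 with the block, median -0.07, camera adjusted p = 0.0462, and adjusted p = 0.331 with an estimated correlation), with Adamts1 at -0.45. That call of the list ended without control replicate 3 (adjusted p = 0.070), RCE replicate 1 (0.0624) and RCE replicate 3 (0.0536). It also ended with no low-value filter (adjusted p = 0.0512), a minimum mean of 5 FPKM (0.446), median-of-ratios scaling (0.0511), quantile normalization (0.0961), array weights (0.0594), GC correction (0.0851) and the replicate block and GC correction together (0.0953) and in the fry rotation test (adjusted p = 0.224). The list median was -0.017 with a minimum mean of 5 FPKM, -0.15 with median-of-ratios scaling and -0.16 with GC correction (also with the block), and -0.045 without control replicate 3. TGF-beta and BMP targets split evenly, 6 higher and 6 lower of 27 (7 and 8 adjusted over the list alone, 10 and 10 with the block). Their median was 0.02 and their mean -0.11, and camera placed them below other genes (adjusted p = 0.0262, and adjusted p = 0.267 with an estimated correlation). Their median was 0.009 with a minimum mean of 5 FPKM, -0.069 with median-of-ratios scaling, -0.029 with quantile normalization, 0.007 with array weights and -0.062 with GC correction (also with the block), and 0.027 without control replicate 1, 0.005 without control replicate 2, 0.010 without control replicate 3, -0.025 without RCE replicate 1 and 9.59e-05 without both replicate 1 libraries. That call ended with no low-value filter (adjusted p = 0.12), a minimum mean of 5 FPKM (0.0722), median-of-ratios scaling (0.080), quantile normalization (0.225), GC correction (0.0851) and the replicate block and GC correction together (0.126). It also ended without control replicate 1 (adjusted p = 0.0814), RCE replicate 2 (0.0535) and RCE replicate 3 (0.0545). The BMP antagonist Grem1 went from 440.3 to 210.5 FPKM (-1.06) and the activin subunit Inhba from 314 to 168 FPKM (-0.90), while the BMP-induced repressor Id2 changed by +0.61.

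Lysosome and autophagy genes were lower in 4 of 45 cases and higher in 0 (the same adjusted over the list alone, 25 lower and 3 higher with the block, median -0.09, camera adjusted p = 4.08e-07, and adjusted p = 0.121 with an estimated correlation), led by the proton pump subunit Atp6v0d1 (-0.30, adjusted p = 0.0107; 0.0509 without control replicate 2). Their median was -0.17 with median-of-ratios scaling and -0.16 with GC correction (also with the block). Metallothioneins and zinc transporters had 1 lower and 0 higher of 17 (0 adjusted over the list alone, 9 lower and 1 higher with the block, median -0.09, camera adjusted p = 0.0322, and adjusted p = 0.141 with an estimated correlation and 0.0528 without RCE replicate 1). That call also ended with no low-value filter (adjusted p = 0.0633) and a minimum mean of 5 FPKM (0.127) and in the fry rotation test (adjusted p = 0.0938). The 1 lower gene, Slc30a1, lost its call in 5 of the 6 fits that left a library out (limma adjusted p = 0.0502 to 0.112). The list median was -0.035 with no low-value filter, -0.17 with median-of-ratios scaling, -0.061 with array weights and -0.17 with GC correction (also with the block), and -0.037 without control replicate 1, -0.053 without control replicate 2 and -0.016 without RCE replicate 1. In the heat-shock list 3 of 24 were higher and 5 lower (4 and 5 adjusted over the list alone, 10 and 7 with the block, camera adjusted p = 0.0602). The inducible HSP70 genes Hspa1a and Hspa1b changed by -2.69 and -2.33, values that are uncertain because reads of these near-identical neighbours cannot be told apart. Dnajb1 was lower (-0.41) and Fkbp4 higher (+0.41). Camera passed the threshold for this list without control replicate 1 (adjusted p = 0.0493), without control replicate 3 (0.0392), without RCE replicate 3 (0.0458) and with array weights (adjusted p = 0.0491).

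The remaining lists did not pass the camera threshold. Targets of ATF4, the transcription factor of amino acid shortage, had 4 higher and 4 lower of 39 (3 and 4 adjusted over the list alone, camera adjusted p = 0.233; 14 and 9 with the block). The 4 lower ones included Vegfa (-0.86), Atf3 (-1.08) and Ddit4 (-1.04), of which Vegfa and Ddit4 are also induced by hypoxia. The unfolded protein response had 0 higher and 1 lower of 24 (the same adjusted over the list alone, camera adjusted p = 0.371; 9 and 4 with the block), the lower one being Ero1l (-0.80). Targets of SRF, MRTF and YAP had 8 higher and 0 lower of 35 (the same adjusted over the list alone, camera adjusted p = 0.428; 18 and 3 with the block), led by the YAP-pathway adaptor Ajuba (+0.78). Camera passed this list, upward, with quantile normalization (adjusted p = 0.0058). Clock genes had 4 higher and 4 lower of 16 (6 and 4 adjusted over the list alone, camera adjusted p = 0.23; 7 and 5 with the block), with the transcription repressor Bhlhe40, which hypoxia also induces, at -2.04 (adjusted p = 4.97e-05), Rora at -0.59, Per1 at -0.88 and Tef at +0.50. Interferon-stimulated genes had 3 higher and 1 lower of 17 (the same adjusted over the list alone, camera adjusted p = 0.991), with Tap1 at +0.53. With the block the counts were 7 and 2. Without control replicate 3 the higher Irf1 (limma adjusted p = 0.0674) and Ddx58 (0.111) and the lower Bst2 (0.0855) lost their calls. Ddx58 lost it when any 1 of the 6 libraries was left out (adjusted p = 0.0706 to 0.146). Of 47 ribosomal protein genes limma called 0 (1 higher and 0 lower at an unadjusted p under 0.05, 3 and 1 with the block, camera adjusted p of the list = 0.364). Without control replicate 1 camera placed this list and oxidative phosphorylation below other genes (adjusted p = 0.0244 and 0.0142), and oxidative phosphorylation also passed with the replicate block and GC correction together (adjusted p = 0.0463). With median-of-ratios scaling the list medians turned from above to below 0 for ribosomal proteins, oxidative phosphorylation, the unfolded protein response, clock genes, interferon-stimulated genes and the targets of ATF4, SRF, TGF-beta and the oestrogen receptor, and for glutathione metabolism, fatty acid synthesis and iron-sulfur cluster and haem synthesis.

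**Figure D4:**
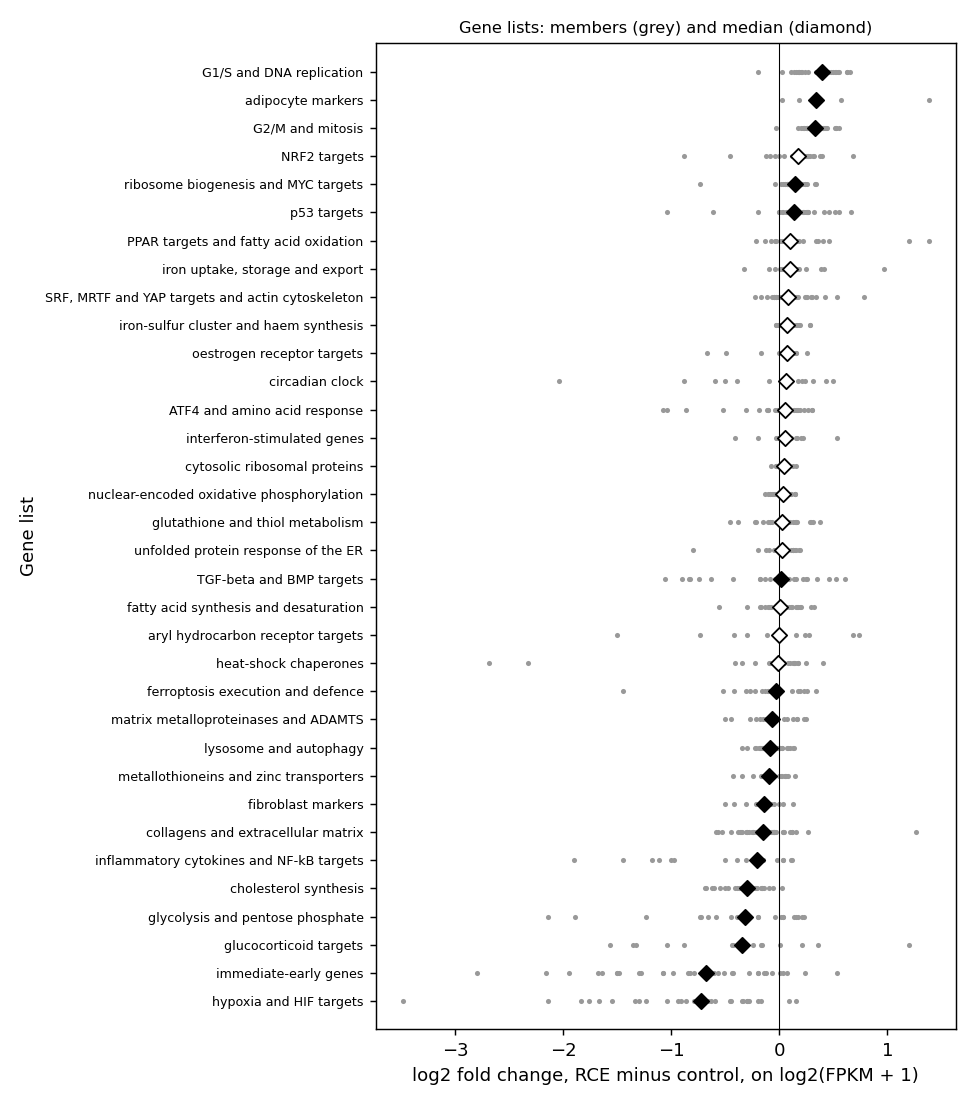
Change of each measured member (grey) and the median (diamond) of the 34 gene lists with at least 5 kept genes, on the log2(FPKM + 1) scale. Filled diamonds mark the 18 lists past a camera adjusted p of 0.05 with the preset correlation, with hypoxia and immediate-early genes lowest and DNA replication highest.

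Markers of other cell types were few. Of the kept genes, macrophage and other blood cell markers numbered 4 (1 lower, Lyz2 at -0.43; 0 higher), endothelial markers 4 (2 lower, Flt1 at -0.45 and Emcn at -0.19; 0 higher) and epithelial markers 3 (1 lower, Krt19 at -0.39; 0 higher). Neural markers numbered 3 (2 higher, Nes and Tubb3, and 1 lower, Stmn2), muscle markers 4 (2 higher, Des and Tnnc1, and 0 lower), and cartilage and bone markers 4 (2 lower, Sox9 and Runx2, and 0 higher). The chondrocyte transcription factor Sox9 went from 11.9 ± 2.4 to 3.49 ± 1.11 FPKM (-1.54, adjusted p = 0.00395). Counts adjusted over the list alone were the same in these 6 lists, which were too short for camera. The replicate block also called Cd14, a macrophage marker, higher (+0.17, adjusted p = 0.0119), and Pth1r of the cartilage and bone list (+0.11, adjusted p = 0.0484), and called Krt18 of the epithelial list lower (-0.28, adjusted p = 0.00443). These changes ran from 0.062 with quantile normalization to 0.31 with array weights for Cd14, from 0.003 with quantile normalization to 0.15 without control replicate 3 for Pth1r and from -0.42 with a pseudocount of 0.1 to -0.13 without RCE replicate 1 for Krt18, and no other alternative called Pth1r. Those of called markers ran from -0.30 with quantile normalization to -0.16 without control replicate 3 for Emcn, from 0.13 with median-of-ratios scaling to 0.26 with array weights for Tubb3 and from 0.049 with quantile normalization to 0.20 with a pseudocount of 0.1 for Tnnc1. Flt1 and Sox9 held without each library in turn. Runx2 lost its call without control replicate 1 (adjusted p = 0.0518), control replicate 2 (0.0771), RCE replicate 2 (0.0992) and RCE replicate 3 (0.087). The call of Emcn ended without control replicate 1 (adjusted p = 0.0572), control replicate 3 (0.0829), RCE replicate 2 (0.0929) and RCE replicate 3 (0.0875). That of Krt19 ended without control replicate 1 (adjusted p = 0.0518), control replicate 3 (0.0883), RCE replicate 2 (0.0606) and RCE replicate 3 (0.0783). That of Stmn2 ended without RCE replicate 2 (adjusted p = 0.0506). Tubb3 lost its call without control replicate 1 (adjusted p = 0.0502), control replicate 2 (0.0907), control replicate 3 (0.0552), RCE replicate 2 (0.111) and RCE replicate 3 (0.0538). It also lost it with median-of-ratios scaling (adjusted p = 0.143), quantile normalization (0.105) and GC correction (0.0939). Des lost it without control replicate 2 (adjusted p = 0.0791), control replicate 3 (0.0774) and RCE replicate 3 (0.0614), and with median-of-ratios scaling (adjusted p = 0.0715). Tnnc1 lost it when any 1 of the 6 libraries was left out (adjusted p = 0.0628 to 0.111). It also lost it with no low-value filter (adjusted p = 0.0597), median-of-ratios scaling (0.183), quantile normalization (0.494), GC correction (0.189) and the replicate block and GC correction together (0.0921).

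The largest rise of the genes named by the rule was that of Dhrs3 (ENSMUSG00000066026, chromosome 4, 144892827 to 144928209), a retinal reductase, from 7.6 ± 0.212 to 33.8 ± 1.53 FPKM (SD, n = 3, log2 change 2.02, SE 0.05, adjusted p = 1.21e-05). The stress-induced Gadd45g went from 59.5 ± 12.7 to 145 ± 30.4 FPKM (+1.27, adjusted p = 0.00616) and its relative Gadd45b changed by +0.89. The others of the 12 were Rasl11b (+1.15), the monooxygenase Fmo2 (+1.12) and the amino acid transporter Slc38a4 (+0.83), besides those given above. Exons of some named genes overlap those of other protein-coding genes. Overlaps on the opposite strand were Ankrd37 with Lrp2bp and Ufsp2, Hspa1a with Gm20481, Junb with Prdx2, Slc11a2 with Gm5475, Lpcat3 with Emg1, Aifm2 with H2afy2, Slc48a1 with Hdac7, Cpox with Gpr15, Fdft1 with Ctsb, Ethe1 with Zfp575, Plk3 with Tctex1d4, Tap1 with Psmb9, Irf1 with Gm17334, Ccna2 with Exosc9, Dkc1 with Mpp1, Cebpd with Spidr, Pth1r with Myl3, Tgm2 with Rprd1b. Overlaps on the same strand, where reads cannot be assigned, were Ugdh with Gm43552 and Cpt1b with Gm44502. Antisense RNAs are annotated across exons of Slc2a1, Bhlhe40, Rgs16, Ereg, Slc25a37, Ndrg1, Dusp5, Eln, Rora, Tef, Des, Txnip, Slc30a1, Twist2. The library kit keeps strand, but whether counting used it is not given in the sources used here, so these values are less certain.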

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

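Counts of higher and lower genes (1910 and 736) stayed within 1.5 times with either pseudocount, without the filter and without the trend. They were 867 and 485 at a mean of at least 5 FPKM (fewer genes tested), 7 and 60 with a log2 limit of 1 (by construction), 911 and 1082 with median-of-ratios scaling, 785 and 857 with quantile normalization, and 5047 and 1731 with array weights. With the replicate block they were 5060 and 1730, and all 2646 genes called without it kept their call and direction. For the settings chosen after seeing the data they were 4360 and 1481 without both replicate 1 libraries, 890 and 1185 with GC correction, and 2745 and 2952 with the replicate block and GC correction. Leaving out 1 library gave 677 to 2029 higher and 399 to 739 lower, and without RCE replicate 1 both rose. For the scalings, the GC correction, array weights, the block and the left-out libraries the cause was not tested.

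Of 18 lists called, 11 kept their call under every alternative except the estimated correlation, with which 2 lists passed, hypoxia targets and glycolysis. With the replicate block and an estimated correlation, chosen after seeing the data, 0 lists passed (hypoxia targets and glycolysis at adjusted p = 0.225). Camera with an estimated correlation tests on few residual degrees of freedom, so these losses need not come from correlation between genes. Over all lists and alternatives 713 values were computed, of which 624 kept direction and side of the threshold, 67 lost the call, 20 gained one and 2 turned: fry moved fatty acid synthesis (median 0.0032) and interferon-stimulated genes (median 0.0485) upward where camera pointed down, since fry does not compare with other genes. Of the gained calls 9 came from fry. They included iron handling (upward, fry adjusted p = 5.82e-04), NRF2 targets (upward, 0.00894) and iron-sulfur cluster and haem synthesis (upward, 0.033). Fry also called aryl hydrocarbon receptor targets (adjusted p = 8.79e-05) and oestrogen receptor targets (0.00198) downward. The replicate block ended the calls of 2 lists, p53 targets and adipocyte markers. For the 178 genes named by the rule, 2877 of 3165 values kept their side, 178 lost and 109 gained the call, and Acsl4 turned (-0.1049 with the replicate block and GC correction; the cause was not tested). The block gave 27 of these genes a call they lacked and changed no other. Of 135 called named genes 100 held without each library in turn. The mean Slc7a11 level, 0.0183 FPKM, was 0.0185 with median-of-ratios scaling. Slc7a11, the gene knocked out in these cells, and Cyp1a1 were both under the minimum for the test, and few fragments lay behind the values of Slc7a11.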

Other observations

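All gene lists and tests in this part were chosen after the result was seen, except the GC content and transcript length tests of the replicate 1 and hypoxia patterns, whose outcome had not been seen, and the lists of the report. A set of ligands that act on the EGF receptor fell with the extract. Of 5 kept genes of the receptor, its ligands and its feedback inhibitor, 4 were lower and 1 higher (median -1.62 on the log2(FPKM + 1) scale). Hbegf went from 53.3 to 16.7 FPKM (-1.62, limma adjusted p = 3.24e-05), Areg from 2.85 to 0.247 FPKM (-1.63), and Ereg and the inhibitor Errfi1 changed by -1.86 and -1.33. The receptor Egfr was higher (0.19, adjusted p = 0.021). The arrestin-related genes Txnip, Arrdc3 and Arrdc4, which the glucose sensor MondoA induces, fell by 1.24, 1.32 and 0.75 (adjusted p = 4.28e-05, 3.24e-05 and 5.77e-04), beside the fall of the glucose transporter Slc2a1.

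Dhrs3, the gene with the largest rise by the rule, is a textbook target of retinoic acid, and one hypothesis is that retinoid-responsive genes rose together. Of 11 kept genes of a list written for this, 5 were higher and 0 lower (7 and 1 with the replicate block, the lower one Rara at -0.13, adjusted p = 0.00875). The higher ones included Tgm2 (0.67) and Crabp2 (0.53). The median change was 0.16, and 0.15 without Dhrs3. Camera on the list without Dhrs3, whose rise prompted it, gave an upward p of 0.149 with the preset correlation and 0.207 with an estimated one, so the test leaves the hypothesis open. It replaced a test of the list with Dhrs3 (p = 0.0315, and 0.0871 with an estimated correlation), which in part restates the rise of Dhrs3.

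Hypoxia targets fell (median -0.7234). A trend on transcript GC content is argued against, since the median was -0.7912 after that trend was removed. A lower density of treated cells, with less local use of oxygen, may account for the fall and would raise targets of YAP. The list of SRF, MRTF and YAP targets did not pass camera in either direction as analysed (median 0.0799). Among the camera alternatives it passed upward only with quantile normalization (adjusted p = 0.0058). The fry rotation test, which does not compare with other genes, also called it upward (adjusted p = 0.0297). Density thus cannot be told apart from an effect of the extract on oxygen use or on HIF, which was not tested. A test of iron chelation on the list median was set aside, since chelation would raise these transcripts and the fall was known before.

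Immediate-early and inflammatory transcripts are short-lived, and a general loss of such transcripts could lower them. The 26 other short-lived transcripts of a separate list had a median change of -0.0186, with 5 higher, Gadd45g, Gadd45b, Id2, Id3 and Irf1, and 6 lower (10 and 12 with the replicate block). Gadd45g and Gadd45b are among the 12 largest rises, and Id2 and Irf1 were also reported as higher above. The count of higher genes is therefore not independent of results already seen. Irf1, on which the count of 5 rests, lost its call without control replicate 3 (adjusted p = 0.0674), RCE replicate 2 (0.0868) and RCE replicate 3 (0.0802) and with quantile normalization (adjusted p = 0.18) and GC correction (0.0781). Camera placed the list below other genes (p = 0.033, and p = 0.345 with an estimated correlation), and changes ran from -1.32 to 1.27, so a loss of part of such transcripts stays open. The bound for this test was made stricter after these values were seen. After the GC trend was removed, the immediate-early list kept a median of -0.7381. The fall was seen in each pair of same-numbered libraries (list medians -0.54, -0.52 and -0.45 over both lists). Lower signalling through growth factor receptors with the extract and a difference in handling at harvest stay open. A test of handling on these pair medians was set aside because no outcome of it could have argued for or against handling, and the GC test of this list was added after that.

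Replicate 1 of both groups stood apart from replicates 2 and 3. Its deviations in the 2 groups correlated at 0.918 across genes, although replicate 1 was deeper than the mean of the others in control (ratio 1.1) and shallower with the extract (ratio 0.794), which argues against depth. A trend on transcript length removed 2.21% of the variance of the deviation, under the 10% set beforehand, and a trend on GC content 11.6%, between the bounds of 10% and 50%, so GC content may hold a small part and is not excluded as a contributor. A separate culture or preparation for number 1 is a candidate explanation that the labels do not record, and no biological explanation was tested.

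The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2646 genes, as many as in 1 of the 10 splits (itself), and the highest of the others gave 0. The 3 others that also part all pairs of numbers gave 0 as well. Every other split holds libraries of both groups on each side, which adds the group difference to the residual spread and works against calls. The 2646 against 0 therefore does not measure how often chance would give as many. For gene lists the real split gave 18, again matched in 1 of the 10, and the highest of the others gave 14. Camera with a preset correlation thus passed many lists in splits where limma called no gene. Part of the group difference stays between the sides of those splits, so they do not show that camera passes lists without cause.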
